A study of Hyaloscypha bicolor with 6 samples.

How the data were processed

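RNA sequencing was used to measure transcripts of the fungus Hyaloscypha bicolor, deposited under its earlier name Meliniomyces bicolor. The fungus is an ascomycete that forms ericoid mycorrhiza, the association of fungal hyphae with root cells of plants of the heather family. There were 2 groups of 3 libraries. One group came from free-living mycelium grown on cellophane over agar, and the other from mycorrhizal roots of Vaccinium myrtillus (bilberry) grown on the same medium. Per the labels' protocols, the medium had a pH of 4.7, contained bovine serum albumin at 0.1 g per litre, and material was taken at day 113. Reads were 150 bp long, per the series' design text. The labels call the libraries biological replicates. They also say that several plates were prepared to supply the mycelium extractions, and do not say whether each extraction had its own plates, so p-values measure the spread between these libraries. RNA was extracted with a phenol procedure from mycelium and with a CTAB (cationic detergent) procedure from roots, per the labels' protocols, so that the extraction method differed with the group in every library.

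Each deposited file held 18619 gene models with their JGI protein number. Per the file headers, the deposited columns were unique gene reads, total gene reads and RPKM. Unique gene reads are raw counts of the reads that the authors' mapping gave to a single gene, and total gene reads are raw counts that also include reads matching further genes. The RPKM values of the authors were recomputed from the total gene reads: the length that each RPKM value implied differed between libraries by at most 0.00123 bp per gene. RPKM was therefore used only to recover the transcript length of 18316 gene models. The aligner, its settings, strand handling and read filters are not given in the sources used here. The number in each RefSeq locus tag of the Melbi2 assembly (K444DRAFT_ followed by a number) matched a JGI protein number for 18598 of the 18619 models, and the recovered length was at most the span of the matched gene in 100% of matched models with a length. The reference table gives no product name for any gene and no name for the scaffolds, so genes are given by locus tag, with positions on an unnamed scaffold of Melbi2. The table lists genes in scaffold order, and it was cut into 78 stretches where the start position fell. A stretch may join scaffolds, so that some genes treated as neighbours may lie on different scaffolds.

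Unique gene reads were taken as the measure after the files were seen, to keep out reads that match several genes. They were tested with edgeR 4.0.16 (R 4.3.3): genes with low counts were removed with filterByExpr, libraries were scaled with TMM, and a quasi-likelihood F test compared the 3 root with the 3 mycelium libraries, two-sided, with Benjamini-Hochberg adjustment over the 16070 genes kept. A gene was called at an adjusted p under 0.05, and a second count required a fitted change of at least 5-fold. Levels are CPM, the unique reads of a gene scaled to the library's total of unique reads without TMM factors, as mean ± SD over 3 libraries. Standard errors of log2 fold changes are approximate, from the fold change and its F statistic. Counting intervals are exact conditional binomial intervals at 95%, cover counting error only, and treat reads as independent molecules. A gene with no read was set to a floor of 3 counts over the group, which is 0.0109 CPM for mycelium and 0.12 CPM for roots. Measures per library were compared with an exact permutation test, for which 3 against 3 libraries cannot give a two-sided p below 0.1.

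The steps were tested on simulated data, with dispersions taken from the fit to these libraries. With 200 of 16070 genes changed, drawn with the means, depths and dispersions of this comparison, 44% of the genes changed 2-fold and 80% of those changed 5-fold were recovered, and 10 of 134 calls (7.46%) were false. This simulation changed a far smaller part of the genes than the 46.21% called in the real comparison, and drew rises and falls at equal odds. Its rates need not hold for the real comparison. The neighbour test called none of 40 random gene sets and did call a set of planted neighbours.

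Before the data were examined, the groups, tests, alternatives and naming rule were fixed. The rule named the genes with the largest rises and falls by fitted fold change among called genes with at least 10 CPM in the higher group and no overlap between groups, and limited them to 2 in each direction if no product names could be had, which applied. One further gene, the most abundant in roots, was chosen after its values were seen. Planned tests of 26 gene lists (such as glycoside hydrolases, peptidases, transporters, and conserved genes to which plant reads could map) needed product names or protein sequences and were not run. The alternatives fixed in advance for the counts were median-of-ratios factors, total-count scaling, no filter, a filter of 10 CPM in 3 libraries, DESeq2 1.42.0, thinning of all libraries to the smallest total, a block for the replicate number, and leaving out each library. Total gene reads, and removal of the most abundant root gene (also for the read shares) or the 10 most abundant, were added after seeing the data. The mean transcript length per read, weighted by unique reads, was also added then. Tests on adjacent genes risen at least 5-fold and on transcript length of 5-fold changed genes were set out before any gene was tested. The files had been seen by then. Thresholds for genes with low reads in one group, the equal-depth detection and the chains of neighbouring genes were chosen after seeing the data. Replicate pairs within a group differed by more than sampling noise (chi-square per degree of freedom of 16.16 or more), so no library was counted as a duplicate. Of the tested genes, 1956 overlapped a neighbouring gene model, and without a stated strand rule their reads may not be separable. Downstream steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.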

Results

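Transcript abundance of H. bicolor was measured in 3 libraries of mycorrhizal bilberry roots and 3 libraries of free-living mycelium. Unique gene reads numbered 89882566, 90706245 and 95624045 in mycelium replicates 1 to 3, and 9229259, 7616730 and 8217681 in root replicates 1 to 3. Mycelium libraries were thus 11.02 times deeper on average (exact permutation test, two-sided p = 0.1, the smallest that 3 against 3 libraries allow). Reads of the host plant were not analysed here. Reads shared between fungal genes made up 0.474% ± 0.031 of total gene reads in roots and 0.241% ± 0.0038 in mycelium (SD, n = 3). The mean transcript length per read was 1661 ± 42.4 bp in roots and 2065 ± 6.43 bp in mycelium, without overlap (exact permutation test, two-sided p = 0.1, the smallest possible), and 1786 ± 19.3 bp and 2066 ± 6.08 bp without the most abundant root gene. The extraction method differed between the groups in every library.

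The comparison of roots with mycelium asked which fungal genes change expression when the fungus lives in the root. Of 16070 genes tested, 3879 rose and 3547 fell in roots, together 46.21% of the tested genes (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Large changes went mostly upward: 977 genes rose and 288 fell at least 5-fold. Small changes went more often downward, with 1403 rises and 2051 falls of less than 2-fold. Between these sizes, 1499 genes rose and 1208 fell from 2-fold to less than 5-fold. The split of all calls depended on scaling: with total counts in place of TMM, which lowered the median log2 fold change from 0.02 to −0.19, 2801 genes rose and 4571 fell, while 860 rose and 361 fell at least 5-fold. The filter set the number of strong changes: among 9757 genes with at least 10 CPM in 3 libraries, 499 rose and 139 fell at least 5-fold.

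**Figure D1:**
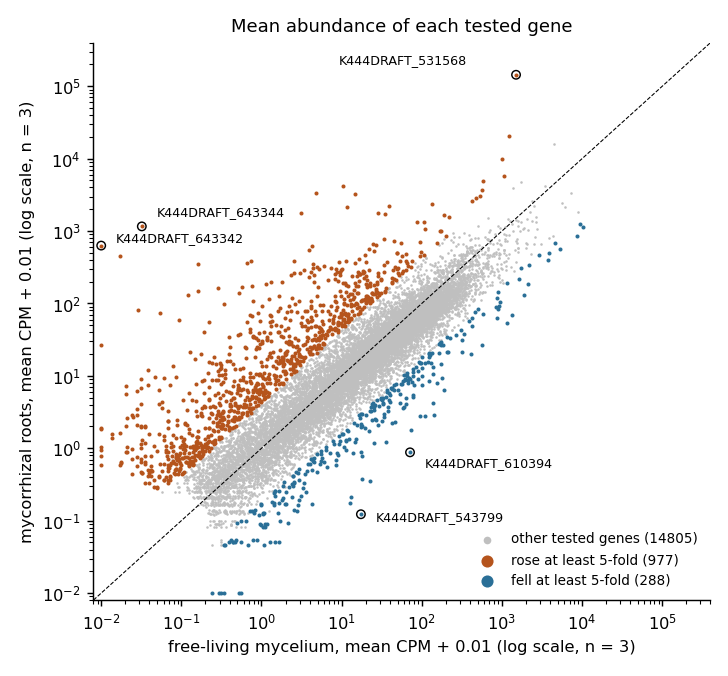
Mean CPM of each tested gene in mycorrhizal roots (vertical) against free-living mycelium (horizontal), both on log axes with 0.01 CPM added, as means of 3 libraries. Orange points are the 977 genes that rose and blue points the 288 that fell at least 5-fold. Grey points are the other tested genes, and the dashed line marks equal CPM. Circles mark K444DRAFT_643342, K444DRAFT_643344, K444DRAFT_543799, K444DRAFT_610394 and K444DRAFT_531568.

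A single gene, K444DRAFT_531568, accounted for 14.4% ± 3.48 of root reads and 0.150% ± 0.025 of mycelium reads (SD, n = 3). The 10 most abundant genes of each library held 22.1% ± 4.38 of its reads in roots and 7.25% ± 1.18 in mycelium (SD, n = 3; exact permutation test, two-sided p = 0.1, the smallest possible). With that gene removed from the reads, the 10 most abundant held 9.54% ± 1.55 in roots and 7.26% ± 1.18 in mycelium, with overlap between the groups (exact permutation test, two-sided p = 0.2, where the smallest possible is 0.1). K444DRAFT_531568 held 17.9%, 11.0% and 14.3% of reads in root replicates 1, 2 and 3, and rose by 6.83 on the log2 scale (approximate SE 0.65, edgeR adjusted p = 9.32e-05). The gene lies at 2797283 to 2798329 of its scaffold, has a transcript of 918 bp in a span of 1047 bp, and shared 0.918% of its reads with other genes. No product name was available for it, and it was picked for its abundance after the values were seen. The genes that rose at least 5-fold held 29.0% ± 5.09 of root reads and 1.45% ± 0.077 of mycelium reads. Without K444DRAFT_531568 they still held 14.6% ± 1.84 and 1.30% ± 0.055. The genes that fell at least 5-fold held 0.979% ± 0.293 of root reads and 8.30% ± 0.646 of mycelium reads. These gene groups were chosen on the same libraries, so their shares describe the size of the change and are not independent evidence of it.

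**Figure D2:**
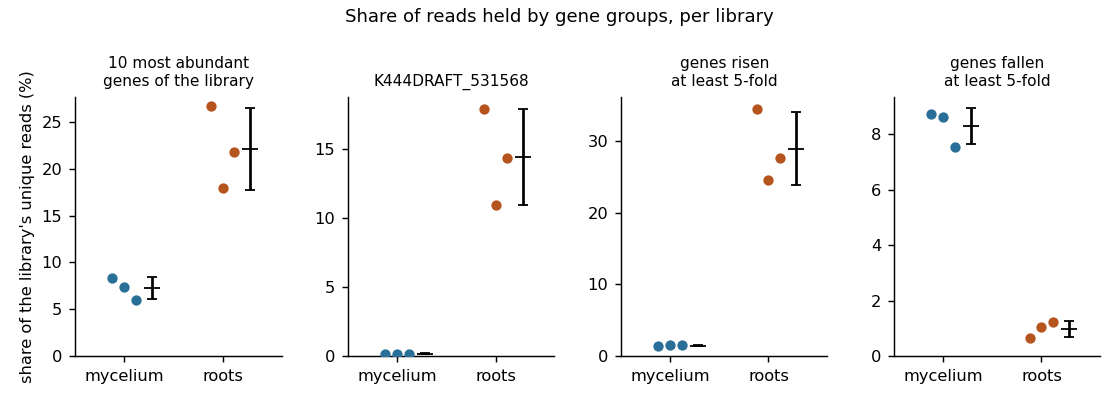
Percent of each library's unique reads held by its 10 most abundant genes, by K444DRAFT_531568, and by the genes that rose or fell at least 5-fold. Points are single libraries of mycelium (blue) and roots (orange), bars are mean ± SD of 3 libraries, and each vertical axis starts at 0; the 10 most abundant genes held 22.1% of root reads and 7.25% of mycelium reads on average, and K444DRAFT_531568 alone held 14.4% of root reads.

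Many of the most abundant transcripts were common to both conditions. Ranked by mean unique reads per kilobase, 52 of the 100 most abundant genes of mycelium were also among the 100 most abundant of roots. Of the 100 most abundant root genes, 66 rose (29 of them at least 5-fold) and 7 fell relative to mycelium. Of the 100 most abundant mycelium genes, 46 fell (15 of them at least 5-fold) and 19 rose. Of all tested genes, 24.14% rose and 22.07% fell. Each ranking used the same libraries as the fold changes, so an excess of rises among top root genes and of falls among top mycelium genes is built in.

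A set of 77 genes went from a mean under 1 CPM in mycelium to at least 10 CPM in roots with a rise of at least 5-fold, whereas 10 genes went the opposite way. Genes with almost no reads in one group also existed on both sides: 22 of the strongly risen genes had at most 3 reads over the 276212856 mycelium reads, and 45 of the strongly fallen genes had at most 3 reads over the 25063670 root reads. The root depth sets a higher floor, so the last count includes genes whose root level is known only to lie under about 0.12 CPM.

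Among genes with at least 10 CPM in the higher group, the 2 largest rises by fitted fold change, the number the naming rule allowed, were those of adjacent genes. K444DRAFT_643342 (351460 to 352252 of its scaffold, transcript of 642 bp in a span of 793 bp) had no read in any mycelium library. In root replicates 1, 2 and 3 it reached 1403, 329.8 and 158.1 CPM. Pooled over libraries this was at least 61600-fold higher in roots, against the floor of 3 counts over the mycelium group (edgeR adjusted p = 0.000443). The bound was 22200-fold without root replicate 1. K444DRAFT_643344 (352651 to 354123, transcript of 1260 bp in a span of 1473 bp) had 6 mycelium reads in all and 2454, 686.1 and 341.1 CPM in root replicates 1, 2 and 3. It rose by 15.85 on the log2 scale (approximate SE 1.32, edgeR adjusted p = 4.54e-05). Leaving out root replicate 1 gave 14.49, leaving out mycelium replicate 2 gave 16.71 and leaving out mycelium replicate 3 gave 15.26. Neither gene shared any read with another gene in these libraries.

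Both genes belonged to an unbroken run of 4 genes, each of which rose at least 5-fold, at 349813 to 358549 of the scaffold, from K444DRAFT_723143 to K444DRAFT_652910. K444DRAFT_723143 rose by 15.78 on the log2 scale (edgeR adjusted p = 1.43e-05), close to the 15.85 of K444DRAFT_643344. The CPM of the 4 genes summed to 3.66, 4.53 and 4.57 in mycelium replicates 1 to 3 and to 5840, 1771 and 995.8 in root replicates 1 to 3. On one side the run ended at K444DRAFT_643340, with a log2 fold change of 0.86 (edgeR adjusted p = 0.0109), and on the other at K444DRAFT_629962, with 0.14 (edgeR adjusted p = 0.506).

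**Figure D3:**
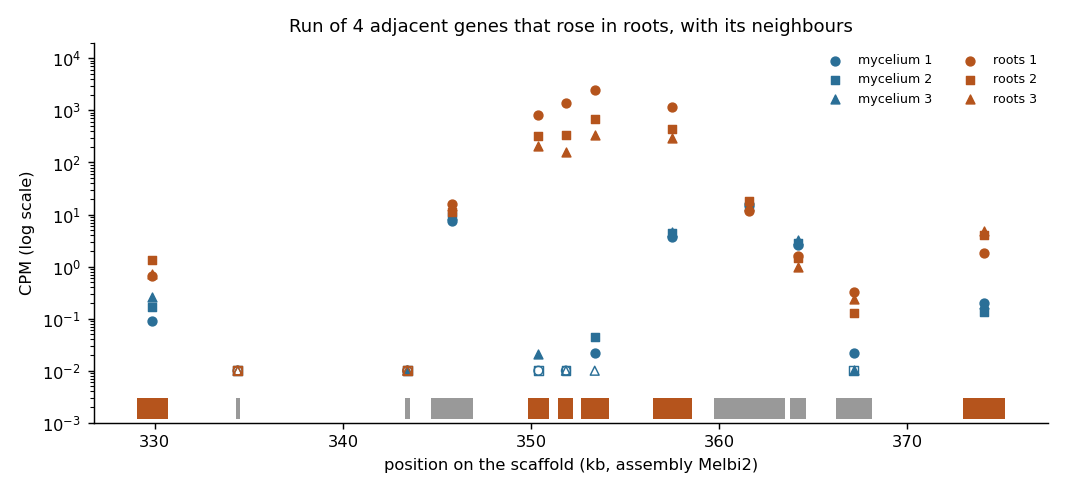
Abundance of the genes around K444DRAFT_643342 by position on the scaffold in kb (assembly Melbi2), with CPM on a log axis; each point is one library of mycelium (blue) or roots (orange), open symbols are libraries with 0 reads drawn at 0.01 CPM, and marker shapes stand for replicates 1 to 3. Bars at the bottom are gene spans, orange where the gene rose at least 5-fold; the run of 4 genes summed to 995.8 CPM or more in every root library and to 4.57 CPM or less in every mycelium library.

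The largest falls under the same conditions were of 2 genes that are not neighbours. K444DRAFT_543799 (6089748 to 6090785 of its scaffold, transcript of 849 bp in a span of 1038 bp) fell from 17.4 ± 12.7 CPM in mycelium to 0.113 ± 0.109 CPM in roots (SD, n = 3), where it had 3 reads in all. The pooled level was 148-fold higher in mycelium, with a counting interval of 50.5 to 716, and edgeR gave an adjusted p of 0.000329. The fitted log2 fold change of −6.91 became −6.16 without mycelium replicate 3 and −7.92 without root replicate 1. K444DRAFT_610394 (866132 to 867558 of its scaffold, transcript of 1379 bp in a span of 1427 bp) went from 71.3 ± 18.5 CPM to 0.869 ± 0.520 CPM and fell by 6.19 on the log2 scale (approximate SE 0.34, edgeR adjusted p = 6.16e-06). None of the named genes overlapped a neighbouring gene model. K444DRAFT_643342, however, lay under 500 bp from each of its neighbours, K444DRAFT_723143 and K444DRAFT_643344, and the strand rule is not stated.

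The fungus expressed a broad set of genes in both conditions. At full depth, 17480 ± 75.4 genes had at least 1 unique read in mycelium and 16967 ± 30.5 in roots (SD, n = 3), in libraries of very different size. After thinning to 7616730 reads per library, a comparison chosen after seeing the data, the order turned, with 16309 ± 105 genes in mycelium and 16892 ± 77.7 in roots (exact permutation test, two-sided p = 0.1, the smallest possible). Genes with at least 1 CPM numbered 13708 ± 174 and 13899 ± 203, a difference that was not distinguishable from the spread between libraries (exact permutation test, two-sided p = 0.2).

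Replicates were closer to each other than to the other group. Pearson correlations of log2 CPM across genes, which are not independent replicates, were 0.988 to 0.992 between mycelium libraries, 0.95 to 0.963 between root libraries and 0.863 to 0.883 between groups. Among 9584 genes with a mean of at least 10 CPM, the median SD of log2 CPM was 0.242 in roots and 0.149 in mycelium. An SD above 1 occurred for 107 of them in roots and 25 in mycelium, with the root libraries being the shallower ones.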

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

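The counts of changed genes, the counts of 5-fold changes and the changes of the named genes were recomputed under 13 alternatives fixed in advance and 3 chosen after seeing the data. The number of changed genes ranged from 5265 with the filter of 10 CPM in 3 libraries to 8134 with DESeq2, against 7426, and 6347 of the calls were shared with total-count scaling. Only that filter, which leaves 9757 genes to test, moved the 5-fold counts by more than 1.5 times: 638 changed genes, 499 rises and 139 falls, against 1265, 977 and 288. The share of rises among all calls (52.24%) turned into a minority with total-count scaling (38.0%), whose median log2 fold change is −0.19, and ranged from 49.18% (without root replicate 1) to 53.21% (without mycelium replicate 3) on leaving out single libraries; among 5-fold changes it stayed between 70.43% and 80.56% under all 16 alternatives. With the replicate number as a block, 7107 genes were called, 6789 of them shared with the fit without it, and 957 rose and 275 fell at least 5-fold; the block ended no call of a named gene. Deviations of same-numbered libraries correlated at 0.058, −0.013 and 0.053, and not every library correlated best with its own number. No pairing by number was seen, but with 3 libraries per group this check cannot exclude one. The named genes kept their direction and stayed under the adjusted p threshold wherever they were tested; K444DRAFT_543799 was removed by the stricter filter, and K444DRAFT_531568 by the alternatives that leave it out. The share of reads in the most abundant genes differed between roots and mycelium by 14.9 percentage points for the 10 highest genes and 11.9 for the 100 highest. With K444DRAFT_531568 removed, a check chosen after seeing the data, the differences were 2.28 and 0.984 points; the gene was picked for its high share in roots, so a drop was built into this check. Alternatives for the gene lists, and the removal of conserved genes to which plant reads could map, were not run because the genes have no product names here. Adjacent pairs of genes risen at least 5-fold, an added result, numbered 112 with the stricter filter and 221 without it, the filter leaving fewer genes to test. The floor was 0.12 CPM over the root libraries and 0.0109 CPM over the mycelium libraries; with all libraries thinned to the smallest total, 779 genes rose and 204 fell at least 5-fold.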

Other observations

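The chains of neighbouring genes, the differences between root libraries and the re-pairing of neighbours were chosen only after results were seen. So were the bootstrap intervals of transcript length and the length per read. Pairs of falls, pairs over all calls and the correlation of length with fold change were not among the tests set out in advance. The other tests were set out before any gene was tested.

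A minority of the genes that rose at least 5-fold lay in long groups along the reference order, in which unnamed scaffolds may be joined. With up to 2 other genes allowed between members, 7 chains of at least 5 such genes were found, with 53 of the 975 placed genes, where 1000 shuffles of positions gave at most 4 chains. The chain with most genes had 13 risen genes over 54.2 kb, from K444DRAFT_691296 to K444DRAFT_631584, whose CPM summed to 1417 ± 489.9 in roots and 49.3 ± 5.68 in mycelium (SD, n = 3). A chain of 12 genes over 28.4 kb, from K444DRAFT_652783 to K444DRAFT_629728, summed to 2890 ± 727.3 CPM and 192.1 ± 20.0 CPM. A chain of 8 genes over 18.3 kb ran from K444DRAFT_661471 to K444DRAFT_585332. An unbroken run of 5 genes over 35.8 kb, from K444DRAFT_670489 to K444DRAFT_604405, reached 16330, 4462 and 2304 CPM in root replicates 1, 2 and 3, and at most 24.6 CPM in any mycelium library. Functions of these genes were not analysed here, since the reference gives no product names.

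Root replicate 1 stood apart for some genes. Of 518 genes that rose at least 5-fold and had at least 10 CPM in roots, 9 were at least 4-fold above both other root libraries in replicate 1 and 8 were at least 4-fold below both, against 0 and 0 for replicates 2 and 3. Of the 8829 other tested genes at that level, 2 were at least 4-fold above both in replicate 1 and 20 below both. Replicate 2 had 0 and 0, and replicate 3 had 0 and 1. The median log2 ratio of replicate 1 to the mean of the others was −0.24 for these other genes and −0.075 for the risen genes. These CPM carry no TMM factors, which were 0.828, 1.011 and 0.959 in root replicates 1, 2 and 3. The negative median and the lean toward lower values in replicate 1 are therefore not separable from scaling.

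More genes rose than fell at least 5-fold in roots, by a ratio of 3.39. Against unequal depth as the whole cause, the ratio was 3.819 with all libraries thinned to the smallest. Against scaling, the lower ratio of 2 other scalings was 2.382, with total counts. Against a single root library, the lowest ratio on leaving out each one was 3.204. A biological response of the fungus to the root remains a hypothesis, since the extraction method differed with the group in every library and plant reads mapping to fungal genes were not tested, including for K444DRAFT_531568.

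Neighbouring genes rose together. There were 221 adjacent pairs in which both genes rose at least 5-fold, against a mean of 52.9 and a highest count of 83 in 10000 shuffles of positions (one-sided permutation p = 0.0001, the smallest they can give). For falls of at least 5-fold there were 43 pairs against a mean of 4.63. Over all called genes the ratio to the shuffled mean was smaller. There were 1320 pairs of rises against a mean of 835.7, which is 1.58 times. Falls gave 1166 pairs against 697.9, which is 1.67 times. The ratios of the 5-fold sets were 4.17 for rises and 9.29 for falls. A larger set leaves less room above its shuffled mean, so these ratios are not directly comparable. Reads matching several genes did not enter the calls, which rest on unique reads. Without genes that share over 1% of their reads, 197 pairs risen at least 5-fold were left (shuffled at most 71). Reads wrongly given to a similar neighbour as unique were not tested. Touching gene models are not the whole cause of these pairs, as 132 lay at least 500 bp apart (shuffled at most 56). The closer pairs are left undecided, since they were taken out of that test. A single root library does not account for the excess either, as the lowest count on leaving out each was 222 (at most 91). The mean absolute difference of log2 deviations between root libraries was 0.3931 within adjacent pairs risen at least 5-fold. This was below the lowest of random pairs (0.509) and of the same genes re-paired (0.538). Co-regulation of neighbours may explain this, as a hypothesis found and tested on the same libraries.

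Transcript length moved with the group when weighted by reads, but not clearly in the medians of strongly changed genes. Median lengths were 1308 bp for genes risen and 1299 bp for genes fallen at least 5-fold, and 1347 bp for the other genes. The differences were −39 bp (bootstrap interval −110 to 17) and −48 bp (−176 to 89), and both intervals include 0. An effect of extraction or fragmentation was set out in advance to shift risen and fallen genes in opposite directions. Both medians shifted in the same direction, which that rule counted against such an effect. The intervals, added later, leave the direction of both shifts undecided, so no conclusion is drawn. Lists matched to the risen genes on mean expression were shorter (95% of medians from 1116 to 1217 bp), with the median of the risen genes at percentile 100, so at matched expression the risen genes were longer; the test was set out to exclude expression level on either side of that range, but a median above it excludes nothing for a shorter length. Mean transcript length per read was 1661 bp in roots and 2065 bp in mycelium, without overlap between libraries (1786 and 2066 bp without K444DRAFT_531568), and longer transcripts tended to lower fold changes among genes not changed 5-fold (Spearman rho −0.119 across genes, which are not independent replicates). An effect of extraction or fragmentation cannot be told apart from the group, since the method differed with it in every library.

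Of the 10 splits of the 6 samples into groups of 3, 1 gave as many changed genes as the real one, namely itself, with 7426 genes, and the highest other split gave 0. Every other split put libraries of both conditions on each side, so the difference between conditions added to its spread and few or no calls were bound to follow. The contrast therefore does not decide whether the calls arose by chance. The splits are also too few for a share under 0.05.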
